A study of Mus musculus with 4 samples.

How the data were processed

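RNA was measured in 4 libraries of C57BL/6 mouse embryos, 1 library per group. Per the labels, zygotes were taken from the oviduct, cultured in KSOM (an embryo culture medium) and treated from the stage with 2 pronuclei with α-KG at 0.15 mM or with 2-HG at 0.3 mM. Each compound had its own negative control, and blastocysts were sequenced. Per the labels' protocols, embryos were treated with Triton X-100 and libraries were made from 1 ng of pre-amplified cDNA. The labels do not state the number of embryos per library, the enantiomer of 2-HG, or whether the libraries kept the strand.

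The values are TPM (length-scaled transcript abundances that share a common total) per gene that the authors computed and deposited, for 53715 genes. The 4 columns summed to between 999891 and 999935. Per the submitters' processing notes, Trimmomatic, HISAT2, Picard, StringTie and DESeq2 were used with the builds mm10 and GRCm38.p6. The notes give no versions, roles or order of these tools. A deposited worksheet of the authors repeats the TPM of 31 genes in the treated libraries. Its 62 values were identical to those of the main table within 1e-06, and it served here only to see which genes the authors had listed. Another 8 columns of that worksheet, from libraries that the labels do not describe, were not used here. No read counts were used, so the depth of each library is unknown and no counting intervals or detection limits are given.

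Gene identifiers were matched by ID to the GENCODE M21 annotation of GRCm38, and 53620 of 53715 matched. 27 gene names that had been stored as dates were recovered by ID. Coordinates, 1-based, and exon overlaps come from that annotation. Each comparison used the difference of log2(TPM + 1) between 2 libraries, for genes with at least 5 TPM in at least 1 of them. The pseudocount of 1 makes differences of low genes smaller than their ratios. A gene passed the size rule when the difference was at least 1 in either direction. There is no replicate in any group, so no test was run, and the difference between both controls served as the yardstick. The controls belong to different treated and control pairs, so this yardstick can include differences between pairs, which the treated comparisons do not. It also shares a library with each treated comparison, so it is not independent of them. The comparison of both compounds used the 10420 genes with at least 5 TPM in at least 1 of the 4 libraries.

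25 gene lists were written before the data were examined. They covered the blastocyst lineages, 2-cell and oocyte genes, cumulus and granulosa cells, oviduct and blood cells, 2-HG and α-KG metabolism, TET and DNA methylation, JmjC histone demethylases, histone methyltransferases, hypoxia targets, glycolysis, the TCA cycle, mitochondrially encoded mRNAs, nuclear OXPHOS subunits, serine and nucleotide synthesis, redox genes, the ATF4 and unfolded protein response, p53 targets, the cell cycle, cholesterol synthesis, ribosomal proteins, silenced germline genes and imprinted genes. Their 571 entries matched 569 genes, counted separately in each list. Some genes are shared between lists, so the lists are not independent. Ldha and Eno1 stand in both glycolysis and hypoxia targets, and Dlst and Idh3g in both 2-HG and α-KG metabolism and the TCA cycle. The 24 entries of the 2-cell list matched 22 genes, the 25 of the oocyte list 24, and the 22 of the redox list 23. The median difference of each list was placed among 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. A list stands outside when it lies beyond the central 95% of them. The percentile describes these libraries only. The minimum of 5 measured members for a percentile was chosen after the data were seen.

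The genes named for each treated comparison were, by a rule fixed at the same time, the 10 largest differences in each direction. They needed at least 10 TPM in 1 library of the pair and a difference larger than that between the controls. Predicted genes, clones and pseudogenes were left out of that ranking, and the extension of this exclusion to further clone prefixes was chosen after the data were seen. The rule added up to 3 members of each list, a fixed set of genes of 2-HG metabolism, TET enzymes and lineage factors, 5 genes per direction between the controls, and 5 genes for each way in which the compounds could go together or apart.

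The procedure was tested on simulated data built on the 9878 genes of the α-KG comparison. It recovered 47% of genes simulated at 2-fold and 98% of genes simulated at 8-fold, and 2.86% of unchanged genes passed the size rule. Of unchanged random lists of 20 genes, 5% lay outside the central 95%. Noise was drawn independently for each gene from a normal distribution, with its spread taken from the α-KG comparison itself. Between the real controls 8.86% of genes passed the size rule, so the 2.86% and 5% are not error rates for these libraries.

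Other settings fixed at that time were pseudocounts of 0.1 and 5, no filter, minimums of 1 and 10 TPM, size rules of 1.5-fold and 4-fold, median-of-ratios scaling over 8164 genes, leaving out 53 mitochondrial and most abundant genes, the mean of both controls, the control of the other compound, named gene models only, and random lists not matched on expression. The mean of both controls was taken on TPM before the log, so it leans toward the higher control. Alternatives chosen after seeing the data left out genes on X or Y, or genes whose exons overlap another gene on the same strand. The splits of the 4 libraries into pairs, the subset at 50 TPM or more, the overlaps expected within 20 bins of expression and the check of overlapping partners were also chosen after seeing the data, as was the choice of lists on opposite sides of the random range for a closer look. The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.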

Results

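Gene expression was measured in mouse blastocysts that had been cultured from the zygote with α-ketoglutarate (α-KG) or 2-hydroxyglutarate (2-HG), to see how each metabolite affects the early embryo. α-KG is the co-substrate of the TET DNA demethylases and the JmjC histone demethylases, and 2-HG carries a hydroxyl group in place of its keto group. The α-KG library came from embryos at 0.15 mM and the 2-HG library from embryos at 0.3 mM, each with its own control library. There are no replicates: each of the 4 groups holds 1 library. At 5 TPM or more, 9196 genes were listed in the α-KG control, 9342 with α-KG, 9417 in the 2-HG control and 9062 with 2-HG. Mitochondrially encoded mRNAs took 4.99%, 4.96%, 4.57% and 5.47% of the TPM in the same order. The sequencing depth is unknown.

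With α-KG, the core lineage factors of the blastocyst were near their control levels, apart from Pou5f1. Cdx2, the trophectoderm factor, was at 15.7 TPM in the control and 16.2 TPM with α-KG, and Gata6, of the primitive endoderm, was at 212 and 208 TPM. Nanog and Sox2, of the epiblast, were at 66.3 and 75.2 TPM and at 8.91 and 9.18 TPM. Pou5f1, which encodes OCT4, was at 47.3 TPM in the control and 28.1 TPM with α-KG, a log2 difference of -0.73 that is under the size rule. The ATF4 and unfolded protein response list had a median of 0.32, the 99.6th percentile of matched random lists, but -0.39 against the mean of both controls.

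Of 9878 genes, 416 were at least 2-fold higher and 306 at least 2-fold lower with α-KG on the log2(TPM + 1) scale, together 7.31%. This balance turned with the control used, to 229 higher and 280 lower against the mean of both controls and 327 higher and 523 lower against the 2-HG control. The mean was taken on TPM, which leans toward the higher control and makes differences lower than a mean of logs would. The genes with the largest higher differences under the fixed rule included Xist, the RNA that silences the X chromosome, at 1.04 TPM in the control and 62.6 TPM with α-KG, and its antisense gene Tsix at 1.75 and 49.7 TPM. These genes overlap on opposite strands, and strand use in the counting is not stated. In the same libraries, Y-linked protein-coding genes summed to 254 and 145 TPM. Slc45a4, a solute carrier gene, was at 0.65 and 44.6 TPM, and Zfp281, a zinc finger factor of pluripotent cells (ENSMUSG00000041483.14, chromosome 1, 136624901 to 136630053 in GRCm38), was at 0.07 and 27.0 TPM. Uqcrc1, a subunit of respiratory complex III (ENSMUSG00000025651.14, chromosome 9, 108936633 to 108949623), was at 12.3 and 258 TPM. Sh3bp5 was at 2.00 and 39.5 TPM, Cables2 at 0.85 and 19.2 TPM, Tgif2 at 0.13 and 10.7 TPM, and Rnf208 at 3.44 and 41.9 TPM. Adat3, a tRNA deaminase subunit listed at 0 in the control and at 11.7 TPM with α-KG, shares exons with Scamp4, which was at 9.27 and 97.7 TPM, and with the clone gene RP24-327D15.11, which went the other way, at 31.2 and 2.03 TPM.

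Among the lower genes, Cox20, an assembly factor of cytochrome c oxidase, was at 76.0 TPM in the control and 2.58 TPM with α-KG. Casp2, a caspase, was at 21.6 and 1.15 TPM, and Dsp, which encodes desmoplakin of the desmosome, was at 80.3 and 12.5 TPM. Sumo3, a small ubiquitin-like modifier, was at 83.3 and 13.0 TPM. Gnl3l was at 19.9 and 1.18 TPM, Rell1 at 23.8 and 1.94 TPM, Golph3l at 19.4 and 1.92 TPM, and Nkiras2 at 25.2 and 2.76 TPM. The small nucleolar RNA genes Snord100, at 34.9 and 0.54 TPM, and Snord16a, at 22.3 and 0.02 TPM, lie within Rps12 and Rpl4. Those hosts were at 340 and 310 TPM and at 2517 and 2735 TPM.

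Of 21 lists with α-KG, 4 lay above the central 95% of random lists and none below, where 1.05 would lie outside for random genes. Between the controls, 7 of 22 lists lay above it and 3 below. The trophectoderm list had a median of 0.20 (percentile 99.2), with 18 of 22 measured members above 0, among them Eomes at 85.0 and 130 TPM and Cldn4, a tight junction gene, at 91.6 and 139 TPM. Elf5 went the other way, at 6.90 and 1.20 TPM. In the ATF4 and unfolded protein response list, Nupr1 was at 1.58 and 7.09 TPM, Herpud1 at 5.95 and 14.0 TPM, and Trib3 at 3.48 and 6.65 TPM. The redox and NRF2 list had a median of 0.17 (percentile 98.6), with Srxn1 at 10.9 and 23.5 TPM and Txnrd1 at 26.5 and 42.2 TPM. The p53 list had a median of 0.28 (percentile 98.9), with Sesn1 at 10.9 and 19.1 TPM and Eda2r at 29.0 and 49.7 TPM.

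Lists tied to the compound itself lay inside the random range with α-KG. The 2-HG and α-KG metabolism list had a median of 0.07, though Dlst, a subunit of the α-KG dehydrogenase complex, was at 10.9 and 60.7 TPM. Idh1 was at 154 and 212 TPM, Idh2 at 126 and 140 TPM, and D2hgdh, a 2-HG dehydrogenase gene, at 7.37 and 9.56 TPM. The TET and DNA methylation list had a median of 0.15, with Tet1 at 40.7 and 41.1 TPM and Tet2 at 98.9 and 114 TPM. The histone methyltransferase list had a median of -0.00 and a mean of 0.11, of opposite sign, with Suz12 at 54.0 and 119 TPM. JmjC demethylases had a median of -0.06, with X-linked Kdm5c at 2.97 and 13.2 TPM and its Y-linked counterpart Kdm5d at 5.49 and 0.99 TPM.

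The 4 lists above the range depended on the control used. Against the mean of both controls, the ATF4 list had a median of -0.39 and the other 3 lay inside the random range, at 0.10 for trophectoderm, -0.02 for redox and 0.08 for p53. The trophectoderm and redox lists also lay inside the range of random lists not matched on expression. Against the 2-HG control, Uqcrc1, Tsix, Cables2, Tgif2 and Rnf208 were under the size rule with α-KG, with Uqcrc1 at a difference of 0.11.

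**Figure D1:**
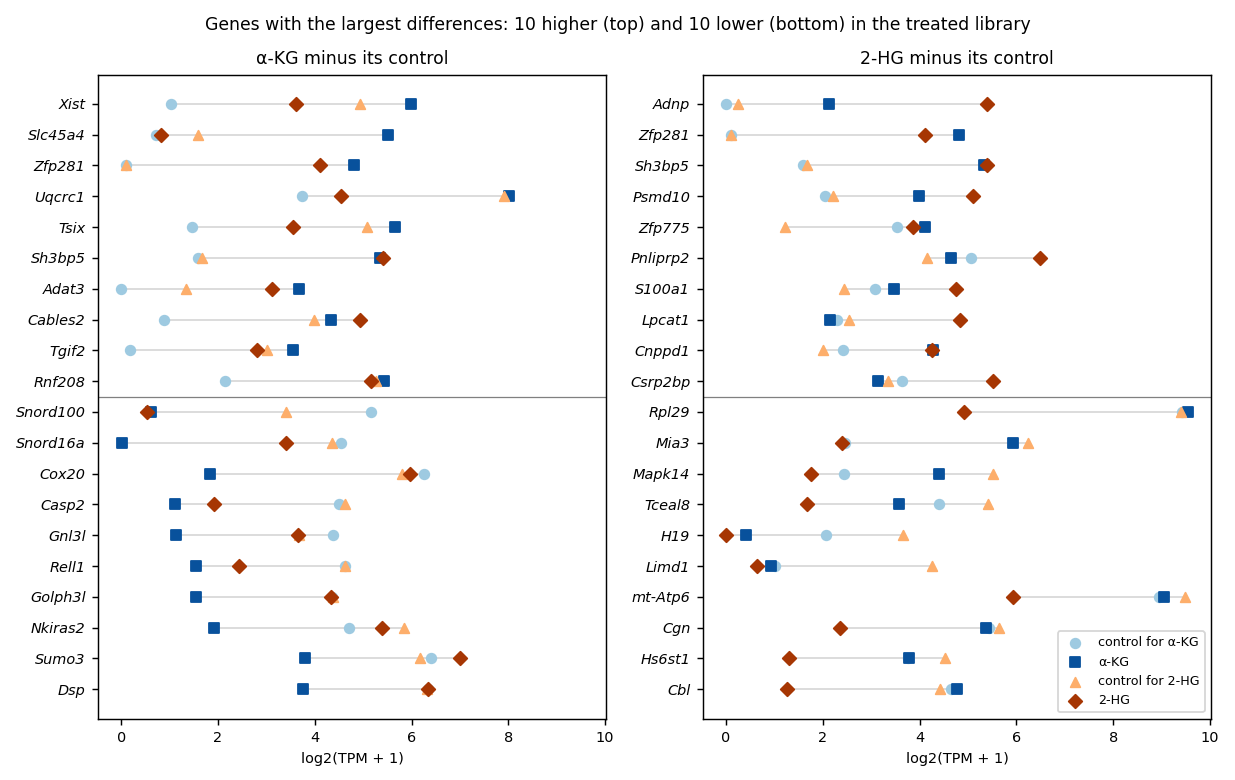
Expression as log2(TPM + 1) of the 10 genes ranked highest (above the line) and the 10 ranked lowest (below the line) with α-KG (left) and with 2-HG (right), in each of the 4 libraries, among genes that are not clones or predicted genes and whose difference exceeds that between the controls. Zfp281 and Sh3bp5 lie apart from both controls in both treated libraries, whereas Uqcrc1 with 2-HG lies near the α-KG control.

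With 2-HG, the list medians of the trophectoderm, the cell cycle, the TCA cycle and nucleotide synthesis were lower than in its control. The trophectoderm list had a median of -0.29, the 0.26th percentile of matched random lists, whose own centre was -0.05. Of its 21 measured members, 12 were below 0 and 9 above, and 2 passed the size rule, both lower: Gata2 at 17.1 TPM in the control and 3.83 TPM with 2-HG, and Cldn4 at 394 and 155 TPM. In both genes the 2-HG control stood apart, since the α-KG control had Gata2 at 4.50 TPM and Cldn4 at 91.6 TPM. Eomes was at 112 and 68.6 TPM, Gata3 at 230 and 180 TPM, and Tfap2c at 58.5 and 39.9 TPM. The keratin genes went the other way, with Krt7 at 32.9 and 56.8 TPM and Krt8 at 2165 and 2523 TPM.

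Of 9834 genes, 232 were at least 2-fold higher and 556 at least 2-fold lower with 2-HG, together 8.01%. The median of all genes was -0.12, and the lists below are set against random lists matched on expression, whose centres differ with the level of expression. With median-of-ratios scaling, 297 genes were higher and 443 lower, which moves the share of higher genes from 29.4% to 40.1%. Against the α-KG control it was 45.1%.

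Among the genes ranked by the fixed rule, which leaves out clone genes, the largest higher difference was that of Adnp, a chromatin protein, at 0.19 TPM in the control and 41.3 TPM with 2-HG. A clone gene that overlaps its exons, RP23-391M18.7, was at 61.9 TPM in the control and listed at 0 with 2-HG. Zfp281 was at 0.07 and 16.2 TPM, Sh3bp5 at 2.19 and 41.2 TPM, and Psmd10, which encodes gankyrin, at 3.66 and 33.3 TPM. Pnliprp2, a lipase gene, was at 16.9 and 88.9 TPM, and Lpcat1, a phospholipid acyltransferase, at 4.86 and 27.6 TPM. S100a1 was at 4.45 and 26.0 TPM, Cnppd1 at 2.98 and 18.0 TPM, Csrp2bp at 9.15 and 45.1 TPM, and Zfp775 at 1.32 and 13.6 TPM.

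Among the genes ranked by the fixed rule, the largest lower difference was that of Rpl29, a ribosomal protein gene, at 679 TPM in the control and 29.3 TPM with 2-HG. Like other ribosomal protein genes, Rpl29 has near-identical processed copies in the genome, so its value is uncertain. The mitochondrial mt-Atp6 was at 718 and 59.9 TPM, and it overlaps mt-Atp8, at 581 and 329 TPM, and mt-Co3, at 405 and 305 TPM. Mapk14, which encodes p38α, was at 45.1 and 2.40 TPM, and Mia3, of collagen export from the endoplasmic reticulum, at 74.1 and 4.26 TPM. Cgn, which encodes cingulin of tight junctions, was at 48.9 and 4.13 TPM, and Cbl, a ubiquitin ligase, at 20.3 and 1.40 TPM. Limd1 was at 18.1 and 0.57 TPM, Hs6st1 at 21.9 and 1.48 TPM, and Tceal8 at 41.9 and 2.20 TPM. H19, an imprinted RNA, was at 11.6 TPM in the control and listed at 0 with 2-HG.

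Of 22 lists with 2-HG, 4 lay below the random range and 2 above, where 1.1 would lie outside for random genes. Between the controls, 3 lay below it and 7 above. Serine, one-carbon and nucleotide synthesis had a median of -0.35 (percentile 0.28), with Mat2a, which makes S-adenosylmethionine, at 43.4 and 18.3 TPM, Gart at 99.7 and 52.3 TPM, and Adsl at 47.9 and 25.6 TPM. Mat2a was at 14.3 TPM in the α-KG control, so its high value stood in the 2-HG control. The cell cycle list had a median of -0.27 (percentile 0.83), with 21 of 27 members below 0, among them Kif11 at 14.7 and 3.49 TPM and Ccne1 at 74.7 and 39.5 TPM, against 39.4 TPM for Ccne1 in the α-KG control. The TCA list had a median of -0.23 (percentile 0.74), with Fh1, fumarate hydratase, at 60.8 and 31.4 TPM. The cholesterol list had a median of 0.09 (percentile 98.6), with Insig1 at 44.7 and 78.7 TPM. Mitochondrially encoded mRNAs had a median of 0.23 (percentile 99.4) but a mean of -0.25, since mt-Atp6 was so low.

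The 2-HG and α-KG metabolism list was close to the edge of the random range with 2-HG, at a median of -0.24 and percentile 2.84. Phgdh, the first enzyme of serine synthesis, was at 224 TPM in the control and 127 TPM with 2-HG, and at 130 and 126 TPM in the α-KG pair, so the 2-HG control stood apart. D2hgdh was at 7.40 and 5.95 TPM. The TET and DNA methylation list lay inside the range, at a median of -0.00 and a mean of 0.04, of opposite sign. Tet1 was at 19.8 and 40.9 TPM and Dnmt3b, a DNA methyltransferase, at 103 and 55.7 TPM. Tet1 was at 40.7 and 41.1 TPM in the α-KG pair, so its low value stood in the 2-HG control. JmjC demethylases had a median of -0.31 (percentile 10.2), with Kdm5a at 41.2 and 23.9 TPM. The histone methyltransferase list had a median of -0.09 (percentile 65.4) and a mean of 0.06, of opposite sign. Of its members, 10 were above 0 and 11 below, with Smyd5 at 10.6 and 43.0 TPM and Ezh1 at 10.5 and 6.19 TPM. Pou5f1 was at 43.3 and 40.6 TPM, Nanog at 62.8 and 44.2 TPM, Sox2 at 2.38 and 1.92 TPM, Cdx2 at 17.3 and 13.5 TPM, and Gata6 at 190 and 161 TPM.

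Against the mean of both controls, the TCA, serine and cell cycle lists lay inside the random range, at -0.11, -0.16 and -0.17. The trophectoderm, mitochondrial and cholesterol lists stayed outside it, at -0.23, 0.20 and 0.40. For cholesterol this setting could only raise the median, so it is no check of that call. All 21 measured cholesterol genes were higher in the 2-HG control than in the α-KG control. Against random lists not matched on expression, the trophectoderm, TCA and cell cycle lists lay inside the range, at percentiles 6.89, 14.1 and 6.51, as did the serine list with a pseudocount of 5, at 4.13. Mia3, Mapk14, Limd1 and Zfp775 were under the size rule when the 2-HG library was set against the α-KG control.

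**Figure D2:**
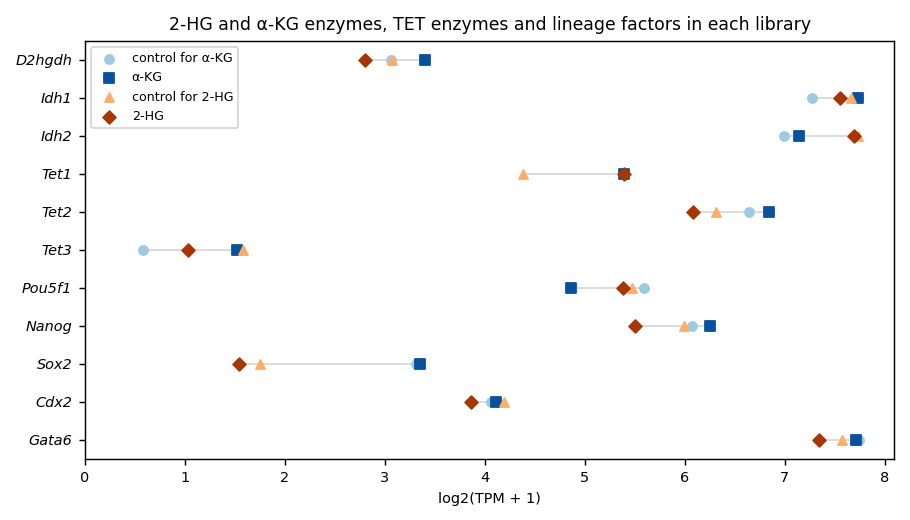
Expression as log2(TPM + 1) of genes fixed in advance (enzymes of 2-HG and α-KG metabolism, TET enzymes and lineage factors) in each of the 4 libraries. Tet1 in the 2-HG control, at 19.8 TPM, lies below the other libraries, and Sox2 is lower in both libraries of the 2-HG pair.

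The controls, which differ in no stated treatment, differed from each other in more genes at the 2-fold rule than either treated library did from its control. Unlike the treated comparisons, this one crosses the pairs. Over 10420 genes, SDs of the log2 differences were 0.637 to 0.671 across pairs, against 0.613 and 0.611 within them. The difference between the controls had a Pearson correlation of 0.47 with that of α-KG and -0.43 with that of 2-HG, since they share a library. Of 9927 genes, 595 were at least 2-fold higher and 285 at least 2-fold lower in the 2-HG control than in the α-KG control, together 8.86%. At a 4-fold rule this order ended, with 149 genes between the controls and 153 in each treated comparison. The ATF4 and unfolded protein response list had a median of 0.83 (percentile 100), with Nupr1 at 1.58 TPM in the α-KG control and 36.9 TPM in the 2-HG control, Herpud1 at 5.95 and 38.7 TPM, and Hspa5, which encodes the chaperone BiP, at 245 and 565 TPM. All 21 measured genes of cholesterol synthesis were higher in the 2-HG control, at a median of 0.67, with Sqle at 10.5 and 32.0 TPM and Fdft1 at 44.5 and 118 TPM.

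Altogether 10 of 22 lists lay outside the random range between the controls, 7 above and 3 below. The others above were imprinted genes at 0.58, redox genes at 0.39, glycolysis at 0.38, 2-HG and α-KG metabolism at 0.32 and the TCA cycle at 0.26. Those below were epiblast genes at -0.43, TET and DNA methylation at -0.25 and ribosomal proteins at -0.22. Sox2 was at 8.91 and 2.38 TPM, and Ldha, lactate dehydrogenase, at 20.5 and 63.0 TPM. Single genes higher in the 2-HG control included Ramp2 at 1.37 and 64.6 TPM (its exons overlap Vps25, at 200 and 75.4 TPM), Haus1 at 7.07 and 142 TPM, Cnnm4 at 0.00334 and 14.7 TPM, and Uqcrc1 at 12.3 and 240 TPM. Atp5a1, which overlaps Haus1 on the opposite strand, went the other way, at 128 and 44.1 TPM. Gapdh was at 1.13 and 44.2 TPM, and its many processed copies make that value uncertain. Lower in the 2-HG control were Gab1 at 38.7 and 3.18 TPM, Vamp8 at 87.9 and 10.9 TPM, Abo at 14.6 and 1.23 TPM, Zfp935 at 18.8 and 2.09 TPM, and Gemin4 at 14.1 TPM and listed at 0.

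**Figure D3:**
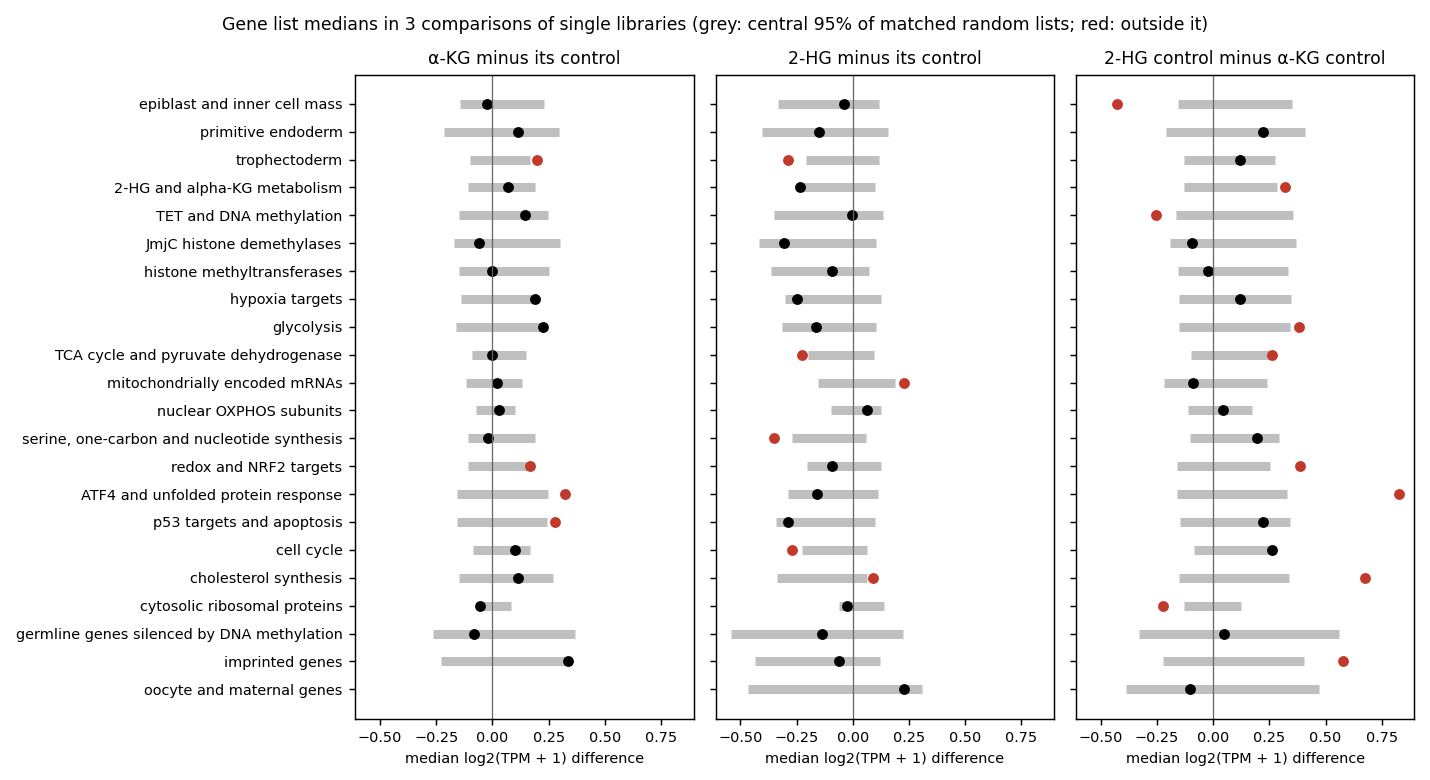
Median log2(TPM + 1) difference of each gene list with α-KG (left), with 2-HG (middle) and between the controls (right). Grey bars span the central 95% of 10000 matched random lists and red points lie outside, which holds for 4, 6 and 10 lists.

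The compounds were set side by side at their different doses, 0.15 mM and 0.3 mM. Zfp281, Sh3bp5, Psmd10, Adnp and Arl8a were at least 2-fold higher with both. Arl8a, a lysosomal GTPase gene, was at 1.21 and 10.1 TPM in the α-KG pair and 1.10 and 8.15 TPM in the 2-HG pair. Adnp was at 0 and 3.34 TPM in the α-KG pair, under the 5 TPM minimum of that comparison. The clone gene that overlaps its exons, RP23-391M18.7, was at 59.5 TPM and listed at 0 in the same pair. Casp2, Rell1, Snord100, Trappc8 and Mmgt2 were at least 2-fold lower with both, and Trappc8, of a vesicle tethering complex, was at 37.4 and 6.20 TPM and at 37.3 and 6.71 TPM. Uqcrc1, Mia3, Iqsec1, Mapk14 and Fxyd5 were higher with α-KG and lower with 2-HG. Tmem70, an ATP synthase assembly factor, was lower with α-KG, at 151 and 40.6 TPM, and higher with 2-HG, at 44.9 and 128 TPM, as were Fbxo18, Flcn, Senp8 and Twistnb. Several of these opposite differences were about as large between the controls, at 4.18 for Uqcrc1, 3.78 for Mia3, -1.72 for Tmem70 and -1.94 for Fbxo18.

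Across 10420 genes, the differences with α-KG and with 2-HG had a Pearson correlation of 0.00 and a Spearman correlation of -0.03, and genes are not independent replicates. Both compounds gave at least 2-fold higher values for 39 genes and lower values for 61, where independent lists would share 11.2 and 20.2. Opposite differences were seen in 87 genes higher with α-KG and lower with 2-HG, against 27.4, and in 29 the other way, against 8.22. Genes of low expression passed the rule more often, and within bins of expression the expected numbers were 31.7, 48.2, 72.3 and 20.7, so same and opposite directions exceeded them to a similar extent. Among 2606 genes at 50 TPM or more in all 4 libraries, 21 passed the size rule with α-KG, 27 with 2-HG and 49 between the controls, and the Pearson correlation was -0.01. The trophectoderm list was above the random range with α-KG and below it with 2-HG, a difference that was not tested. Both of these calls were lost against random lists not matched on expression, at percentiles 94.5 and 6.89. Of the 3 ways to part the 4 libraries into pairs, the split of treated from control libraries gave 55 genes with both libraries of one side at least 2-fold above both of the other. The split that crosses compound and treatment gave 57, and the split by compound pair gave 97.

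Of the cumulus and granulosa cell list, Amhr2 alone reached 5 TPM, at 3.68 and 5.15 TPM in the α-KG pair and 4.44 and 8.45 TPM in the 2-HG pair. Of the oviduct and blood cell list, Cd68, a macrophage and lysosome gene, was at 10.3 and 30.0 TPM in the α-KG pair and 19.3 and 18.5 TPM in the 2-HG pair, and Muc1 at 2.55 and 1.79 TPM and at 7.53 and 9.62 TPM. Zfp352, a 2-cell stage gene, was listed at 0 in both controls, at 7.28 TPM with α-KG and 0.27 TPM with 2-HG, and Zfp809 of the same list was at 64.1 and 38.9 TPM in the α-KG pair and 66.2 and 57.1 TPM in the 2-HG pair. Arg2, also of that list, was lower with both compounds, at 4.89 and 1.46 TPM and at 7.97 and 2.78 TPM. The maternal genes Khdc3 and Ooep were well expressed in all 4 libraries. Khdc3 was at 508 and 425 TPM in the α-KG pair and 473 and 422 TPM in the 2-HG pair. Ooep was at 50.2 and 42.0 TPM and at 37.0 and 30.8 TPM. With 2-HG, the oocyte and maternal list had a median of 0.23 (percentile 94.1), with 3 of 5 measured members above 0. Padi6 was at 5.84 and 9.38 TPM and Tle6 at 14.0 and 18.8 TPM in that pair. With α-KG, only 4 members were measured, at a median of -0.18. Of the lists inside the random range in both treated comparisons, some came near its edge with α-KG. These were glycolysis at 0.22 (percentile 97.46), imprinted genes at 0.34 (percentile 96.7), hypoxia targets at 0.19 (percentile 96.2) and ribosomal proteins at -0.05 (percentile 3.80). With 2-HG they stood at -0.16, -0.06, -0.25 and -0.03, with hypoxia targets at percentile 5.7. The medians with α-KG and 2-HG were -0.02 and -0.04 for the epiblast list, 0.11 and -0.15 for primitive endoderm, and -0.08 and -0.14 for germline genes silenced by DNA methylation. Nuclear OXPHOS subunits stood at 0.03 and 0.06, with a mean of -0.08, of opposite sign, with 2-HG. Inside the range with α-KG alone were the TCA list at -0.00, mitochondrially encoded mRNAs at 0.02, serine and nucleotide synthesis at -0.02, the cell cycle at 0.10 and cholesterol synthesis at 0.11. The mean had the opposite sign for the first 4 of these, and for the epiblast list with 2-HG. Inside it with 2-HG alone were the ATF4 list at -0.16, redox genes at -0.09 and p53 targets at -0.29.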

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

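The tests of the deviating library and of handling shared within pairs were chosen after the result was seen. The median difference of the trophectoderm list was 0.20 with α-KG and -0.29 with 2-HG, which differ in sign between the compounds. The difference was not tested, and each value rests on 1 library and its own control. Against random lists not matched on expression both lay inside the central 95%, at percentiles 94.5 and 6.89, and without mitochondrial and the most abundant genes the α-KG value was also inside, at 97.4.

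The genes with the largest differences, such as Adnp, Adat3 and mt-Atp6, were often low or overlapped other genes. The partners of mt-Atp6 were lower with 2-HG too, at log2 differences of -0.82 for mt-Atp8 and -0.41 for mt-Co3. The fall of mt-Atp6 was thus not matched by a rise in them. Of genes past the size rule with 2-HG, 12.1% had exons overlapping another gene on the same strand, above the 9.68% upper bound of matched draws, and both other comparisons also exceeded theirs. When genes were ranked by expression and parted into 3 equal groups, the share past the size rule in the highest group was at most 0.193 of that in the lowest. Reads assigned differently between overlapping genes and low expression may therefore account for part of these differences. Most genes past the rule had no overlap on the same strand. Overlap on opposite strands was not counted, and whether the libraries kept the strand is not stated. An effect of either compound on these genes stays open, as untested.

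Xist was at 1.04, 62.6, 29.7 and 11.2 TPM in the α-KG control, α-KG, 2-HG control and 2-HG libraries. Y-linked protein-coding genes summed to 254, 145, 211 and 230 TPM, so the library with the least Xist had the most Y-linked RNA and the one with the most Xist had the least. The sex makeup of the embryos in each library is therefore a candidate explanation for Xist. A change in Xist expression with α-KG stays open, since the number and sex of the embryos are not given in the labels.

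At the 2-fold rule, the controls differed in more genes than either treated library did from its control. Scaling by median of ratios left 838 genes past the size rule between them, against 703 and 740 in the treated comparisons, and leaving out mitochondrial and the most abundant genes left 999 against 870 and 881, so both argue against these as the whole cause. The number of libraries whose distance to every other library exceeded those among the rest was 0. The 2-HG library had the largest distances, with SDs of 0.667 and 0.671 to the α-KG pair, but 0.611 to its own control. Handling shared within a pair would lower that last distance, so this count cannot decide whether a single library deviated. In 97 genes both libraries of one pair lay at least 2-fold above both libraries of the other pair, more than under either other split, so handling shared within a pair may contribute. Embryo batch and library batch cannot be separated from the pair, and no biological explanation was tested.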

How the results depend on the processing

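The alternatives without genes on X or Y and without overlapping genes were chosen after seeing the data, and they left all 4 gene counts within 1.5 times their main values. So did median-of-ratios scaling and leaving out mitochondrial and the most abundant genes. Counts of genes past the size rule are given in the order α-KG, 2-HG, control against control, and both compounds in the same direction; the main values are 722, 788, 880 and 100. A pseudocount of 5 gave 289, 321, 398 and 24, and a pseudocount of 0.1 moved only the last, to 159. No filter and a minimum of 1 TPM both gave 2225, 2189, 2256 and 210, since a difference of 1 needs at least 1 TPM. A minimum of 10 TPM gave 397, 443, 547 and 54. A size rule of 4-fold gave 153, 153, 149 and 15, and one of 1.5-fold gave 1902, 2246, 2432 and 379. The filters changed which genes entered, while the pseudocounts and size rules acted on the same genes through the size of the differences or the threshold.

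Of 10 lists outside the random range in the treated comparisons, all stayed outside with another filter or scaling. The mean of both controls put 6 inside the range and reversed the ATF4 and unfolded protein response list with α-KG to -0.39, since the 2-HG control had the higher values. Random lists not matched on expression put 5 inside the range (trophectoderm and redox with α-KG; trophectoderm, TCA and cell cycle with 2-HG). A pseudocount of 5 put the serine list with 2-HG inside, and leaving out mitochondrial and the most abundant genes put 1 of 9, trophectoderm with α-KG, inside and gave no value for the mitochondrial list. The cause was not tested. Of 40 named differences, 9 were under the size rule against the other compound's control. Against the mean of both controls, taken on TPM, 1 was just under it, Rnf208 at 0.998. The rule that named these genes required a difference larger than that between the controls, so none could change sign against either. Replicate alternatives were not run, because each group holds 1 library. Each compound has 1 treated library and 1 control, so its own comparison holds a single pair and no spread between pairs. Fits that pool both compounds, or both controls, as 1 group were not run. Depth is unknown, so the precision of low values cannot be given.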

Other observations

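The genes in this part were chosen after their values were seen. Ly6a, a cell surface gene, was at 403 TPM in the α-KG control, 310 with α-KG, 352 in the 2-HG control and 1528 with 2-HG. Several well expressed genes were lower in both treated libraries than in both controls. Tpd52 was at 441 and 151 TPM in the α-KG pair and 494 and 80.5 TPM in the 2-HG pair, Nras, a small GTPase gene, at 53.9 and 18.9 TPM and at 62.3 and 25.8 TPM, and Mbnl3, a splicing regulator, at 121 and 49.3 TPM and at 162 and 53.8 TPM. Larp4b was higher in both, at 33.6 and 114 TPM and at 43.1 and 90.6 TPM. The split of treated from control libraries, which holds Tpd52, Nras, Mbnl3 and Larp4b, gave 55 such genes. The crossed split gave 57 and the split by pair 97, so such genes were no more frequent than under the other splits.

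Other genes went with the pair and not with the compound. Ddit3, which encodes the stress factor CHOP, was at 51.0 and 82.8 TPM in the α-KG pair and 172 and 228 TPM in the 2-HG pair, and Atp6v0b, a proton pump subunit, at 250 and 324 TPM and at 656 and 686 TPM. All 21 measured cholesterol synthesis genes were higher in the mean of the 2-HG pair, at a median difference of 0.74, and Cyp51 was at 5.74 and 6.65 TPM and at 18.9 and 21.5 TPM.

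Of the genes the authors listed in their worksheet on these samples, Ehmt2, a histone methyltransferase, was at 23.8 and 39.5 TPM in the α-KG pair and 23.7 and 28.9 TPM in the 2-HG pair. Suv39h1 was at 8.28 and 7.91 TPM and at 24.3 and 15.7 TPM, and Hif1a at 39.1 and 51.8 TPM and at 38.7 and 58.4 TPM. How the authors chose that list is not stated, so it is not treated as independent evidence.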
